A study of Mus musculus with 6 samples.

How the data were processed

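Polyadenylated RNA was sequenced from bone-marrow-derived macrophages of wild-type female BALB/c mice, 6 to 12 weeks old. Per the labels' protocols, marrow cells grew for 8 days in medium with 20% L929 fibroblast conditioned medium, were polarized for 24 hours with IL-4 and IL-13 at 10 ng/mL each, and then received 200 µg/mL of nanoparticles or the vehicle for 24 hours. The series title gives the particles as poly(lactide-co-glycolide), and the treatment label of these samples, PEMA, is not explained in the sources used here. Libraries were made with poly(A) enrichment and read as pairs of 151 bp.

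The authors deposited 1 table of gene-level expected counts for the 6 libraries, with no scaling for depth. The submitters' processing notes name cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3, MultiQC 1.7 and the build GRCm38, without giving the role of each. The annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart. All 6 columns held whole numbers of 0 or more, although RSEM's estimates need not be whole, so the rounding was in the deposited values. RSEM divides reads that match several genes between them, so genes with near-identical copies (ribosomal protein genes and their pseudogenes, ferritin genes, Hspa1b) carry uncertain values. The table had 55491 rows, of which 4 were reporter constructs with 0 counts and were left out. Of the 55487 gene rows, 55141 matched GENCODE M21 by identifier, which gave coordinates on GRCm38, gene types and exonic lengths, and 27851 had 0 counts in every library.

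Total counts ran from 41974957 to 69450411 per library, so that 3 counts equalled 0.0432 to 0.0715 CPM (here, counts scaled to the library total). Intervals and such limits cover counting error only. Every NP library was deeper than every PBS library.

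edgeR's quasi-likelihood test, fixed as the main test before the data were examined, and DESeq2, meant as its alternative, were not run. The layout of the deposited table, with quoted names that hold spaces, kept the automatic check of its unit from reading the columns. The unit therefore rests on the labels, the processing notes and a separate reading of the values, and count tests that need a checked unit were not used. limma voom, which had been listed as an alternative, became the main test. It was fitted with limma 3.58.1 in R 4.3.3 on the group alone, with 4 residual degrees of freedom per gene, trimmed-mean (TMM) factors between 0.979 and 1.02, and Benjamini-Hochberg adjusted p under 0.05. The TMM factors and the low-count filter were written out in R after their published definitions. The filter kept genes with at least 0.171 CPM, which is 10 counts at the median depth, in at least 3 libraries and at least 15 counts in total, which left 14478 genes. Where libraries were left out, it asked for as many libraries as the smaller group then held, so the tested genes changed. voom added 0.5 to each count. Log2 fold changes are NP minus PBS. CPM values of single tested genes use the library sizes over tested genes scaled by the TMM factors. The CPM of the filters, of the 3-count limits, of Y genes and of sums over olfactory and vomeronasal receptor genes or ribosomal pseudogenes use the unscaled library totals.

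A total of 43 gene lists for macrophage functions, RNA quality and other cell types was fixed before the data were examined, and 38 had at least 5 tested members. They were tested with camera, with a preset correlation of 0.01 between genes and adjustment over the lists, and again with an estimated correlation and with fry. With an estimated correlation camera had only the 4 residual degrees of freedom, so a list missed there is not shown to be unchanged. Genes named in the text were the 10 largest increases and the 10 largest decreases among genes with adjusted p under 0.05, a mean of at least 5 CPM, no overlap between groups and no predicted symbol. A fixed panel of genes was to be printed whatever its result, and in each list members with the smallest p were named; a few genes that this rule takes are not reported here. Genes outside this rule are marked as chosen after their values were seen.

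On counts simulated from the PBS means with a dispersion of 0.000556, over 15629 genes, the voom fit recovered 91 of 100 genes changed 2-fold and 73 of 100 changed 1.25-fold, with 5 false calls among 169. In 10 simulations without any change at most 2 genes and 0 lists were called in total. The simulated genes were drawn independently and with the same dispersion. In the data the estimated correlation within a list reached 0.937 (cell cycle). The simulations therefore give no rate of false calls for correlated lists or for genes that vary more. Within groups, the chi-square per gene between libraries ran from 4.92 to 19.6, so no pair of libraries differed by as little as sampling noise. Alternatives were other scaling factors, sample weights, filters, a replicate block, a library number covariate, leaving out libraries and other list tests. limma-trend, keeping PBS 1 as the only PBS library, and a covariate for counts in olfactory and vomeronasal receptor genes were added after seeing the data. Python 3.11.15 with pandas 2.3.3 read the table and matplotlib 3.10.9 drew the plots.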

Results

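Gene expression was measured by poly(A) RNA sequencing in mouse bone-marrow-derived macrophages that had been polarized with IL-4 and IL-13, the cytokines of alternative (M2) activation. The libraries fell into 2 groups of 3: cells treated for 24 hours with 200 µg/mL of poly(lactide-co-glycolide) nanoparticles (NP), and cells given PBS as the vehicle. The comparison asked how the particles changed expression in M2-polarized macrophages. Total counts were 56265590, 41974957 and 51079771 in PBS 1 to 3, and 69450411, 61057868 and 60702163 in NP 1 to 3. The labels do not say whether the samples were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

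In macrophages given nanoparticles, 49 of 50 cell cycle genes, 17 of 27 alternative activation genes, 26 of 32 interferon-induced genes, 11 of 16 complement genes, 13 of 17 macrophage identity genes and 56 of 65 ribosomal protein genes were lower than in macrophages given PBS. Higher expression was found in 18 of 23 glycolysis genes and 19 of 32 NRF2 oxidative stress genes, and in 12 of 24 cholesterol synthesis genes, 27 of 56 lysosome genes and 6 of 11 osteoclast markers, while 13 lysosome genes and 3 osteoclast markers were lower. The set test camera called these 11 lists with a preset correlation between genes and 0 of them with an estimated correlation, where adjusted p was 0.39 for glycolysis, 0.635 for cholesterol synthesis and lysosome and 0.401 for the others. With an estimated correlation camera had only 4 residual degrees of freedom, and correlations within lists of up to 0.937 (cell cycle), and so little power. The cholesterol synthesis and osteoclast calls were lost without NP 2 (adjusted p = 0.0575 and 0.056), and the lysosome and osteoclast calls when genes shared between lists were left out (0.0563 and 0.383). Mrc1, the mannose receptor, fell from 1165 ± 106 to 467 ± 24 CPM (SD, n = 3 each), and Mki67, a marker of dividing cells, from 659 ± 10.4 to 290.0 ± 56.1 CPM. Gpnmb, a glycoprotein of lysosomes and melanosomes, rose from 1028 ± 71.9 to 2297 ± 33.4 CPM, and Hmox1, the heme-degrading enzyme heme oxygenase 1, from 213 ± 2.06 to 397 ± 37.8 CPM.

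Of 14478 genes tested with limma voom, 5964 passed adjusted p of 0.05, with 2872 higher and 3092 lower in NP. Most of the changes were small: 582 genes passed with at least a 2-fold change, 195 higher and 387 lower. In 7714 genes (53.3%) the NP and PBS libraries did not overlap, against 10% by chance. The first principal component held 84.5% of the variance over 9928 genes and separated the groups, with NP 2 at 9.3 and NP 1 and NP 3 at 20.2 and 16.0. PBS 2 and PBS 3 held 138 and 153 CPM in olfactory and vomeronasal receptor genes, against 9.7 to 12.5 CPM in the other 4 libraries. With PBS 1 as the only PBS library, an alternative chosen after seeing the data, 2972 genes passed and 463 of them by at least 2-fold. The 2-fold count was 1988 without PBS 1 (1803 of them lower), 298 without NP 1 and 353 without NP 3. In these fits 16054, 15832 and 15816 genes were tested.

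Among genes of at least 5 CPM, the largest increases were in Ebf3, a transcription factor, Dio2, the enzyme that activates thyroid hormone, and Inhba, the activin A subunit. Their log2 fold changes were 2.60 (SE 0.23), 2.47 (SE 0.09) and 2.44 (SE 0.18). Dio2 reached 151 ± 15.2 CPM in NP against 27.3 ± 2.92 in PBS (SD, n = 3 each). Eef1a2, Bex1, Cd200, Lat, Gprc5b, Mreg and Dok7 rose by log2 values between 1.76 (Dok7) and 2.40 (Eef1a2). Dio2 lies on chromosome 12 at 90724552 to 90738438 and Inhba on chromosome 13 at 16011851 to 16031621 (GRCm38, GENCODE M21). The largest decreases were in Siglec1, the sialic acid receptor CD169 of macrophages, and Il4i1, an amino acid oxidase induced by IL-4. They had log2 fold changes of -2.32 (SE 0.15) and -1.86 (SE 0.06). Rnase4, Ccnb2, Cldn11, Plxdc2, Depdc1b, Clec10a, Klhl33 and Hr fell by values between -1.49 (Hr) and -1.69 (Rnase4). Siglec1 lies on chromosome 2 at 131069220 to 131086765 and Il4i1 on chromosome 7 at 44816387 to 44840809. Adjusted p (limma voom) was at most 2.01e-04 in these 20 genes.

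**Figure D1:**
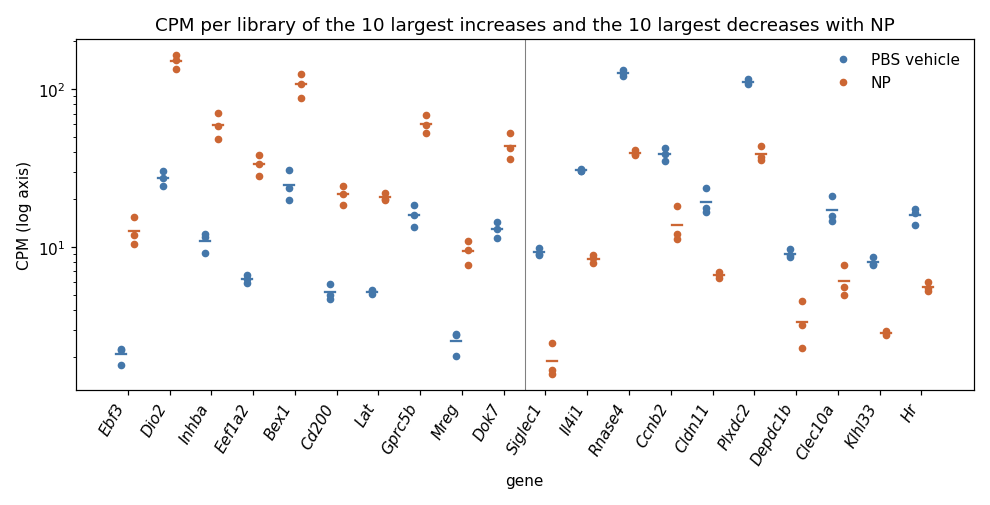
CPM (counts relative to the TMM-scaled library size, log axis) of the 10 largest increases and the 10 largest decreases in each library, with PBS vehicle in blue and NP in orange; each point is 1 library and each bar the mean of 3. The groups do not overlap in any of these genes, as with Dio2 at 27.3 CPM in PBS and 151 in NP.

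The cell cycle list fell almost throughout, with 49 of 50 tested members lower and 0 higher, over all genes and adjusted over the list alone. Its median log2 fold change was -0.99, and 24 members fell by at least 2-fold. Nusap1 and Cenpf, needed for the mitotic spindle and kinetochore, had values of -1.38 and -1.32, Mki67 of -1.20 (SE 0.11) and Tpx2, a spindle factor, of -0.81. The list's adjusted p from camera was 6.03e-21, and adjusted p = 0.401 with an estimated correlation. The list moved with the position of the libraries: NP 2, the NP library nearest to PBS, reached a median of 0.719 of the change in NP 1 and NP 3, over 43 of its genes.

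Of 27 tested members of the alternative activation list, 17 fell and 2 rose, or 18 and 2 adjusted over the list alone. Mrc1 and Mgl2, C-type lectin receptors, fell by log2 values of -1.32 (SE 0.06) and -1.33 (SE 0.13). Fcgr2b, the inhibitory Fc receptor, had a value of -0.89 and Flt1 of -0.47. Arg1, arginase 1, went from 374 ± 29.3 to 269 ± 63.9 CPM (log2 fold change -0.50, limma adjusted p = 0.0172), a call that was lost without PBS 2 (adjusted p = 0.0673), NP 2 (0.0506) or NP 3 (0.108). Retnla (-0.57, limma adjusted p = 0.0578) and Chil3 (-0.15, limma adjusted p = 0.601), a resistin-like molecule and a chitinase-like protein induced by IL-4, did not pass. Retnla passed without PBS 1 (adjusted p = 0.0278), and the sign for Chil3 turned without NP 2. The 2 members that rose were Ccl22 (1.70), a chemokine at 3.9 CPM in NP and 1.2 CPM in PBS, and Itgb3 (1.34), an integrin subunit that the osteoclast list also holds. Ccl24 was lower (-0.84). The list had adjusted p = 6.38e-05 in camera and adjusted p = 0.401 with an estimated correlation.

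The type I interferon list had 26 of 32 members lower and 0 higher, also when adjusted over the list alone, with a median log2 fold change of -0.62. Irf9, a subunit of the interferon-activated transcription complex, had a value of -0.40, Cmpk2 of -1.43, Usp18 of -0.74 and Parp14 of -0.42. Of 16 complement members 11 fell and 0 rose, again the same adjusted over the list alone. The subunits of C1q fell together, with C1qa at -1.13, C1qb at -1.22 and C1qc at -0.96. The camera adjusted p was 1.98e-08 for interferon and 3.85e-05 for complement. Both had adjusted p = 0.401 with an estimated correlation.

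Inflammatory lists also had more genes lower than higher. Of 24 members of the inflammatory (M1-type) list, 14 fell and 3 rose, or 14 and 4 adjusted over the list alone. Il1b, which encodes interleukin 1 beta, fell from 19.2 ± 1.20 to 9.24 ± 0.211 CPM (SD, n = 3 each), and the neutrophil chemokines Cxcl2 and Cxcl3 had values of -1.38 and -2.48. Cd86, a costimulatory molecule, rose (0.40), while Tnf (-0.19, limma adjusted p = 0.125) and Cd40 (-0.11, limma adjusted p = 0.414) did not pass. Of 18 chemokines 14 fell and 2 rose, or 15 and 2 adjusted over the list alone, with Cxcl16 at -0.33 and Ccl6 at -0.81. In the inflammasome list 13 of 21 fell and 2 rose, the same adjusted over the list alone, with P2rx7 at -0.25 and Nlrp3 at -0.75. In the toll-like receptor list 16 of 31 fell and 4 rose, or 17 and 5 adjusted over the list alone, with Tlr4 at -0.61, Tlr8 at -0.58 and Tlr7 at -0.93. The camera adjusted p was 0.00732, 0.00107, 0.00302 and 0.0187 for these 4 lists in turn, and each had adjusted p = 0.401 with an estimated correlation. The toll-like receptor list was not called without PBS 1 (adjusted p = 0.201) or without the low-count filter (0.0551). When genes shared between lists were left out, the inflammatory, chemokine and toll-like receptor lists were not called (adjusted p = 0.45, 0.065 and 0.107).

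Macrophage identity genes fell in 13 of 17 members and rose in 2, also adjusted over the list alone. Adgre1, the F4/80 antigen, had a log2 fold change of -0.65 (SE 0.04) and Csf1r, the receptor for CSF1, of -0.59 (SE 0.05). In camera the list had adjusted p = 8.69e-05, and adjusted p = 0.401 with an estimated correlation. Phagocytic and scavenger receptors fell in 15 of 29 members and rose in 3, the same adjusted over the list alone (camera adjusted p = 0.0103, and adjusted p = 0.401 with an estimated correlation). Stab1, a scavenger receptor, had a value of -0.77. Msr1, scavenger receptor A, was lower by a small margin (-0.20, limma adjusted p = 0.0159) that was lost without PBS 1, PBS 2, NP 1 or NP 3. Cd36, the receptor for oxidized lipoproteins, rose (0.28). Immune regulation genes fell in 12 of 27 members and rose in 3, the same adjusted over the list alone, with Siglec1, Il10ra (-0.86), Gas6 (-0.84) and Sirpa (-0.28) lower. Cd274, which encodes PD-L1, rose (1.17, SE 0.09). By at least 2-fold, 3 members of the immune regulation list rose and 1 fell. Cd274 and Il1rn (named after its values were seen) were among those that rose. Migration and chemokine receptor genes fell in 14 of 25 members and rose in 5, or 15 and 5 adjusted over the list alone, with Itga4 at -0.57, Selplg at -0.41 and Itgb1 at -0.23. The migration list had a median of -0.17 and a mean of -0.07. By at least 2-fold, 2 of its members rose, Itgb3 among them, and 3 fell. The camera adjusted p of the immune regulation and migration lists was 0.0468 and 0.0487, and both had adjusted p = 0.401 with an estimated correlation. Immune regulation was not called without PBS 1, PBS 3 or NP 2, without PBS 2 and NP 2, with PBS 1 as the only PBS library, with sample quality weights, with limma-trend or with a covariate for olfactory and vomeronasal receptor counts (adjusted p = 0.0525 to 0.199). Migration was not called without PBS 1 or NP 1, without the low-count filter, with the library number covariate or with limma-trend (adjusted p = 0.0502 to 0.223), phagocytic receptors were not called without PBS 1 (0.112), and none of these 3 lists was called when genes shared between lists were left out (0.181, 0.0535 and 0.345).

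Glycolysis genes rose in 18 of 23 members and fell in 3, the same adjusted over the list alone. Slc2a1, the glucose transporter GLUT1, had a log2 fold change of 0.46, Pgam1 of 0.44 and Hk3, a hexokinase, of 0.48. In camera the glycolysis list had adjusted p = 3.33e-05, and adjusted p = 0.39 with an estimated correlation. Of 60 oxidative phosphorylation genes 3 were higher and 1 lower (2 and 0 adjusted over the list alone), with a median log2 fold change of 0.02 and camera adjusted p = 0.405. camera called this list as higher without the low-count filter (adjusted p = 0.00215), with PBS 1 as the only PBS library (0.0279) and with a covariate for the olfactory and vomeronasal receptor counts (0.0236). NRF2 and oxidative stress genes rose in 19 of 32 members and fell in 2, or 20 and 2 adjusted over the list alone. Hmox1 had a value of 0.89 (SE 0.06), and the redox enzyme genes Srxn1 and Txnrd1 had 0.61 and 0.39. Adjusted p in camera was 7.19e-05, and adjusted p = 0.401 with an estimated correlation. In the iron and heme list 11 of 20 rose and 5 fell, the same adjusted over the list alone, with the iron transporter Slc11a1 at 0.59, Fth1 (ferritin heavy chain) at 0.45 and Flvcr1, a heme exporter, at 0.48. Its median was 0.16 and its mean -0.07, and the call (camera adjusted p = 0.0487) had adjusted p = 0.492 with an estimated correlation. It was lost without PBS 2 (adjusted p = 0.058), without PBS 2 and NP 2 (0.0831), with sample quality weights (0.0655), with limma-trend (0.119) and when genes shared between lists were left out (0.326).

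Lysosome genes rose in 27 of 56 members and fell in 13, or 28 and 15 adjusted over the list alone. Gpnmb had a value of 1.16 (SE 0.05), Cd63, a lysosomal membrane protein, of 0.48, the protease gene Ctsd of 0.40 and Atp6v1c1, a subunit of the proton pump V-ATPase, of 0.51. Autophagy genes rose in 14 of 33 members and fell in 2, the same adjusted over the list alone, with the receptors Tax1bp1 and Sqstm1 at 0.46 and 0.54 and Atg12 at 0.56. Cholesterol biosynthesis genes rose in 12 of 24 members and fell in 1, the same adjusted over the list alone. Sqle, squalene epoxidase, had a value of 0.48, Insig1 of 0.46 and Hmgcs1, HMG-CoA synthase, of 0.23. Abca1, the cholesterol exporter, fell (-0.55), in an LXR target list with 6 of 14 members lower and 3 higher (8 and 4 adjusted over the list alone, camera adjusted p = 0.0658). The LXR list was called as lower without PBS 2 (adjusted p = 0.0307), without PBS 2 and NP 2 (0.0155) and with PBS 1 as the only PBS library (0.0279). The camera adjusted p was 0.0157 for lysosome, 0.0399 for autophagy and 0.00898 for cholesterol biosynthesis, with adjusted p = 0.635, 0.624 and 0.635 with an estimated correlation. The autophagy call was lost without PBS 2 (adjusted p = 0.058), under a strict filter of at least 1 CPM in 3 libraries (0.059) and with limma-trend (0.106), and the cholesterol biosynthesis call without NP 2 (0.0575) and without PBS 2 and NP 2 (0.157). When genes shared between lists were left out, lysosome and autophagy were not called (adjusted p = 0.0563 and 0.0535).

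**Figure D2:**
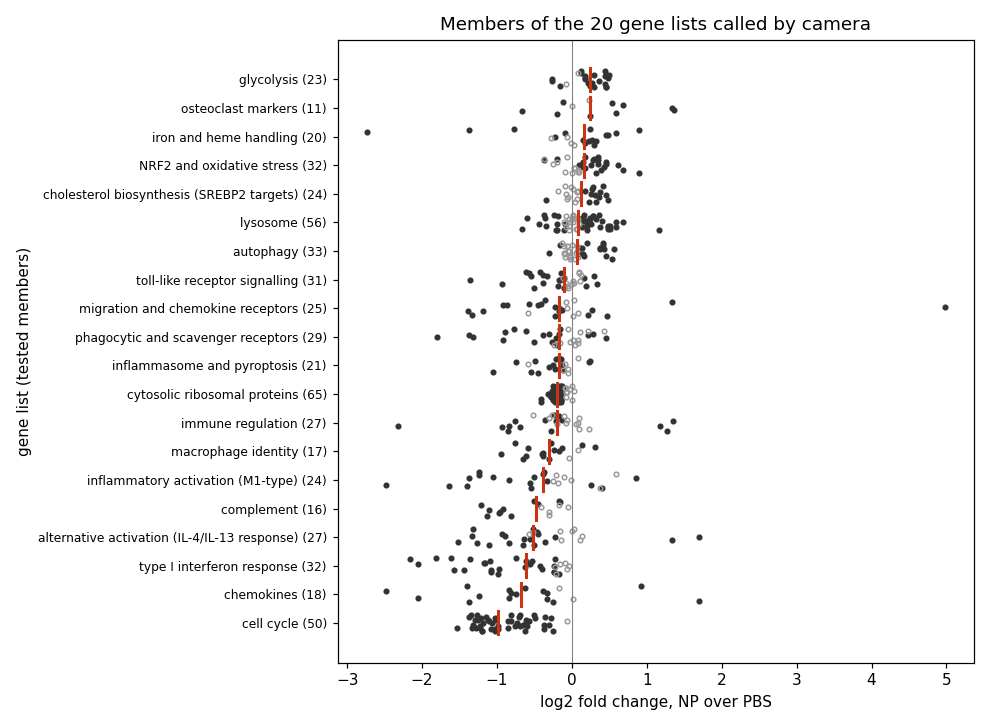
Log2 fold change (NP over PBS) of each tested member of the 20 gene lists called by camera with a preset correlation; filled points passed adjusted p of 0.05 over all genes, open points did not, and red bars are list medians. The median was -0.99 in the cell cycle list and 0.24 in the glycolysis list. None of the 20 calls held with an estimated correlation, where camera had 4 residual degrees of freedom and little power.

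Markers of other cell types and RNA quality moved in part. Osteoclast genes rose in 6 of 11 members and fell in 3, the same adjusted over the list alone, with Car2, carbonic anhydrase 2, at 1.36, Ckb at 0.53 and Ctsk, cathepsin K, at 0.68 (camera adjusted p = 0.0361, and adjusted p = 0.401 with an estimated correlation). The osteoclast call was lost without NP 2 (adjusted p = 0.056), without PBS 2 and NP 2 (0.0718), with sample quality weights (0.0736), under the strict filter (0.0552) and when genes shared between lists were left out (0.383). Dendritic cell genes rose in 5 of 12 members and fell in 0, also adjusted over the list alone (camera adjusted p = 0.162). The list was called as higher with PBS 1 as the only PBS library (adjusted p = 0.0151) and with the covariate for olfactory and vomeronasal receptor counts (0.0117). Ly75, an endocytic receptor, had a value of 1.49. Ccr7, a chemokine receptor of migrating dendritic cells, had 85 counts over the NP libraries and 1 over the PBS libraries, a ratio of 66.4 with an exact 95% interval from 11.6 to 2650 for counting error. Cd74, the class II invariant chain, fell (-0.63) and H2-Ab1, a class II chain, did not pass (0.21, limma adjusted p = 0.148). Ribosomal protein genes fell in 56 of 65 members and rose in 0, or 59 and 0 adjusted over the list alone, by a median of -0.19. Rps4x and Rps20 both had a value of -0.41 (camera adjusted p = 5.03e-14, and adjusted p = 0.401 with an estimated correlation). Mitochondrially encoded genes made up 2.43 to 2.58% of counts and were lower in 1 of 13, or 0 adjusted over the list alone (camera adjusted p = 0.216).

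The remaining lists were not called by camera with the main settings, and their counts are over all genes with those adjusted over the list alone in brackets. In class II presentation 1 of 10 rose and 5 fell (1 and 6), in class I presentation 3 of 17 rose and 5 fell (4 and 5), and in endocytosis 6 of 36 rose and 12 fell (6 and 13). In the hypoxia list 7 of 25 rose and 4 fell (7 and 4), among them Vegfa at 0.41. In the fatty acid oxidation and lipid droplet list 9 of 34 rose and 7 fell (9 and 7), with the lipid droplet genes Plin2 and Hilpda at 0.60 and 1.20, and camera called it as higher without the low-count filter (adjusted p = 0.048). In the p53 list 7 of 26 rose and 12 fell (7 and 12), in the integrated stress response 10 of 35 rose and 13 fell (11 and 15), and in the unfolded protein response 4 of 25 rose and 11 fell (4 and 11). In matrix and growth factor genes 8 of 34 rose and 8 fell (8 and 8), with Spp1, osteopontin, at 0.64 and Igf1 at -0.46, while Tgfb1 did not pass (-0.07, limma adjusted p = 0.127). In arginine and polyamine metabolism 3 of 18 rose and 7 fell (3 and 7), and in immediate early and heat shock genes 8 of 24 rose and 4 fell (8 and 4). Of monocyte markers 0 of 7 rose and 3 fell (0 and 3, and the list was called as lower without NP 1 with camera adjusted p = 0.034), of neutrophil markers 1 of 6 rose and 2 fell (1 and 3), and of fibroblast markers 2 of 9 rose and 3 fell (2 and 3). In the 5 lists with fewer than 5 tested members, 1 of 2 mast cell, 2 of 3 eosinophil and 1 of 2 B cell markers fell, 1 of 4 T and NK cell markers rose and 1 fell, and the 1 erythroid marker did not pass. Nos2 (1 to 8 counts per library), Il6 (2 to 8), Il10 (0 to 4), Marco (0 to 3) and Ccl17 (0 to 3) had too few counts to be tested.

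camera called 20 of the 38 tested lists, 7 higher and 13 lower, and with an estimated correlation 0 were called, with 1 list (glycolysis) at an unadjusted p under 0.05. With its 4 residual degrees of freedom the latter had little power. The estimated correlations counted as well. The cell cycle list, with 49 of 50 members lower and a correlation of 0.937, had an unadjusted camera p of 0.156 there. Glycolysis, with a correlation of 0.0118 and the same degrees of freedom, had an unadjusted camera p of 0.0103. fry, which tests whether a list's genes move one way and does not compare them with other genes, called 27.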

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

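The tissue marker test, the scaling test, the test of NP 2 by rising and falling genes and the counts over other splits were set up before their results were seen, and the other tests were chosen only after.

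PBS 2 and PBS 3 stood out by counts in genes mostly outside the comparison, since only 11 of 2003 olfactory and vomeronasal receptor genes were tested. The 2003 genes held 138 and 153 CPM, against 12.5 CPM in PBS 1 and 9.7 to 11.9 CPM in the NP libraries. PBS 2 and PBS 3 had counts in 23259 and 22976 genes, against 20073 to 20587 in the other libraries. Depth is argued against, since the lower of both values in CPM was 11.1 times the highest of the others. RNA of a tissue that expresses these receptors is argued against as well, since 12 marker genes of olfactory tissue, neurons and testis had counts equal to 0.667% of the receptor counts and Omp, abundant in olfactory neurons, had 4 and 6 counts against 5 to 9 in the others, although the neuronal genes Snap25 (19 and 12), Stmn2 (18 and 16) and Syt1 (8 and 7) exceeded the 0 to 2 counts of the others. Genomic DNA of the cells is a candidate source that stays open: the excess was present on all 17 chromosomes with at least 10 of these genes, and not in the Y chromosome genes of these cells, which the labels give as female, and no biological explanation was tested. The 1562 Y genes held 40.0 and 38.7 CPM in PBS 2 and PBS 3, 39.2 in PBS 1 and 64.9 to 75.2 in the NP libraries, nearly all in Gm47283 and Gm21860 (named after their values were seen), and the other 1560 held 0.643 and 0.509 CPM against 0.626 to 0.906.

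NP 2 lay nearer to the PBS libraries than NP 1 and NP 3. It was not the only NP library set apart, since NP 1 lay beyond the others. As a share of the change in the other NP libraries, NP 1 reached a median of 1.22 in 451 genes that fell. In 235 genes that rose its lower quartile was 1.11. NP 3 reached 1.05 in 524 genes that fell and 0.961 in 274 that rose. NP 2 reached a median of 0.731 in 319 genes that rose and 0.728 in 617 that fell. The difference was 0.00279 (bootstrap interval -0.0125 to 0.0268). PBS material mixed into NP 2 and a smaller response give such a difference alike, so these cannot be told apart by it. Of 4 lists with at least 10 such genes, the share was highest, 0.993, in 10 alternative activation genes (quartiles 0.817 to 1.07). It was lowest, 0.601, in 10 interferon genes (quartiles 0.51 to 0.671), a difference of 0.392. In 11 lysosome and 43 cell cycle genes it was 0.758 and 0.719, near the values over all genes. The extremes were picked after the values were seen, and no such spread was computed for NP 1 or NP 3. The shares were thus unequal between lists, which does not decide against a mixture as the whole cause. A batch of the libraries numbered 12 and 13 (NP 2 and PBS 2) that shifts both alike is argued against, since over 976 genes NP 2 was shifted by a median of -0.292 of the change between the groups (quartiles -0.391 to -0.176) and PBS 2 by 0.0816 (quartiles 0.00143 to 0.148), while PBS 1 and PBS 3, measured alike over 891 and 954 genes, had -0.0629 and 0.000341. A smaller response of that sample, a batch that acts differently on each group, or a mixture, alone or together with other differences, may remain.

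Ribosomal protein genes fell together by a small amount, with a median log2 fold change of -0.19 over 65 genes (quartiles -0.23 to -0.15). With 1 library left out the median ran from -0.2 to -0.165. It was -0.144 with PBS 1 as the only PBS library and -0.13 with the receptor gene covariate. Part of the fall may thus rest on the PBS libraries with the excess of receptor gene counts. Gene length is argued against, since 1615 other genes of the same exonic length and at least 50 CPM had a median of 0.0214 (quartiles -0.10 to 0.14). A shift of reads to ribosomal pseudogenes is argued against, since the summed CPM of 314 of these was lower in every NP library, by a log2 ratio of -0.15. The median was -0.19 or lower under each of 4 scalings. These scalings differed little, with medians from -0.228 to -0.191, so they cannot decide whether the scaling itself was off. A change of scaling moves all genes of a library alike, so it cannot produce the gap to the other genes of the same length. A response of the treated cells may be one explanation of that gap, as a hypothesis found and tested on the same data.

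In the 10 splits of the 6 libraries into 3 and 3, the real groups gave 5964 changed genes against at most 2 in any other split, and 582 changed at least 2-fold against at most 2. For the gene lists the real groups gave 20 calls and another split up to 14. Each other split set libraries of both groups on each side in unequal numbers, so part of the difference between NP and PBS stayed between its sides. The rest of that difference added to the spread within sides, which holds gene calls down. These splits therefore give no background rate for gene or list calls. In each case 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05.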

How the results depend on the processing

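All alternatives named here were set before the data were examined, except limma-trend, keeping PBS 1 alone and the receptor gene covariate, which were chosen after seeing the data. edgeR's quasi-likelihood test and DESeq2 were planned and not run, and unrounded counts gave no separate value because the deposited values were whole. None of the 5964 genes passed in the opposite direction under any alternative run. The 5964 calls became 5955 to 7056 under other factors and sample weights, 4662 without the low-count filter, 5869 under the strict filter, 5671 with the library number covariate and 4077 to 6466 with 1 library left out. limma-trend happened to give the same number, with 5891 genes shared. PBS 1 as the only PBS library gave 2972, where fewer samples were fitted and the lone library was assumed to vary like the NP libraries, and the receptor gene covariate gave 3339. The 2-fold count of 582 became 329 under the strict filter, where fewer genes were tested. It ranged from 298 (without NP 1) to 1988 (without PBS 1). The rise without PBS 1 lay in the decreases, 1803 against 387, while the increases were 185 against 195. Without PBS 2 or PBS 3 there were 373 and 355 decreases. The rise thus came where PBS 2 and PBS 3 were the only PBS libraries. More genes were tested without PBS 1, 16054 against 14478, and 14696 and 14754 without PBS 2 or PBS 3. The filter asked for as many libraries as the smaller group held, so counts in PBS 2 and PBS 3 alone were then enough. Of the 582 genes, 533 still passed without PBS 1, so the count of 1988 does not describe the same genes. The excess of counts in PBS 2 and PBS 3 described above is a candidate source, but the genes behind the added decreases were not examined. The cause of the other shifts was not tested. Of 20 lists, 0 were called with an estimated correlation, where camera had little power. When genes shared between lists were left out, 10 were called, where lists were smaller, and 16 to 20 with 1 library left out. Calls were gained by 5 further lists in some settings, and their camera adjusted p over the settings ran from 0.00215 to 0.502 for oxidative phosphorylation, 0.0155 to 0.255 for LXR targets, 0.0117 to 0.791 for dendritic cell markers, 0.034 to 0.196 for monocyte markers and 0.048 to 0.518 for fatty acid oxidation and lipid droplets.

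The replicate numbers gave no sign of pairing: same-numbered deviations from the group means correlated at -0.0899, -0.237 and -0.267. Differently numbered ones ran from -0.187 to 0.426. Deviations within a group of 3 sum to 0, so these values depend on each other and cannot decide whether samples were paired. With the number as a block, 5022 genes passed, 594 of them at least 2-fold, and 17 lists, where immune regulation (camera adjusted p = 0.0555), migration (0.0516) and iron and heme (0.0508) were not called. Over 170 named genes and all alternatives, 2815 values kept their direction and side of the threshold, 61 lost the call and 5 gained it, and those that turned sign had not passed. Many of these genes were named for a small p or a large change in the same data, so they keep calls more readily than others. Of all 5964 calls, 4044 (without NP 3) to 5249 (without NP 2) were kept with 1 library left out, and 3255 with the receptor gene covariate. Chil3 (-0.15) ranged from -0.40 (without NP 1) to 0.11 (without NP 2) and was 0.17 without libraries 12 and 13, and Cd40 (-0.11) was 0.0221 with PBS 1 alone and 0.0313 with the covariate. The cause was not tested. Of the calls of at least 2-fold, 100 of the increases and 167 of the decreases were in genes under 1 CPM, where depth limits most.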

Other observations

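Further genes changed in the NP libraries, and those named in this paragraph were chosen after their values were seen. They were picked singly and speak for no gene list, though some are list members. Il1rn and Il10ra belong to immune regulation, Cx3cr1 to migration and Csf1r to macrophage identity. Cdkn1c, an inhibitor of cyclin-dependent kinases, rose from 17.8 to 59.4 CPM (log2 fold change 1.75, SE 0.07), Gadd45g by 1.09, Gadd45b by 1.03 and Btg3 by 1.08, while of the p53 list, which holds Gadd45b, 12 of 26 members fell and 7 rose (camera adjusted p = 0.44). Csf2rb, the shared beta chain of the receptors for GM-CSF, IL-3 and IL-5, rose by 0.76 and Il7r, the member of the T and NK cell list that rose, by 0.64, while the receptor genes Il10ra (-0.86) and Csf1r (-0.59) fell. Csf2rb has a close paralog, so its value is uncertain. Dnmt3a, a DNA methyltransferase, rose by 0.74, Npy, a neuropeptide, by 1.08, and Il1rn, the antagonist of the interleukin 1 receptor, by 1.35, from 117 to 296 CPM. Alox5, the enzyme that starts leukotriene synthesis, and Cx3cr1, the fractalkine receptor, had values of -1.32 and -1.33. limma voom adjusted p was at most 0.00157 in these genes.

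Within the lysosome list, 10 of 13 V-ATPase members rose and 0 fell, while 17 of the other 43 rose and 13 fell. Mean log2 fold changes were 0.26 ± 0.19 and 0.06 ± 0.35 (SD over genes). The hypothesis that V-ATPase subunits rose more than other lysosome genes was tested after the values were seen: the difference was 0.20 with a two-sided permutation p = 0.0493 from 100000 resamples. This is across genes, which are not independent replicates, and the p lies close to the threshold, so the difference may be chance.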
